A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

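RNA from 2 strains of budding yeast was measured on 12 spotted arrays of 2 colours, each of which set the RNA of 1 culture sample against a reference RNA. The labels name the reference only as such and give neither its source nor the dyes. Wild type (strain DBY8778) and a strain lacking YPL230W (USV1, which encodes a zinc finger protein) had 6 arrays each, with 1 array per strain and time point. Wild type was sampled at 0, 3, 5, 7 and 9 hours and 1 day, and the deletion strain at 0, 2, 5, 7 and 9 hours and 1 day. The labels place all samples in a stationary phase course and do not say from which event the hours were counted. Nothing in the labels says that a strain was grown in more than 1 culture, so p-values do not measure the spread between cultures.

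The values analysed were log2 ratios that the authors deposited, 1 per gene and array. The scanner software, background correction, spot filter and normalization behind them are not given in the sources used here. The log base is not stated and was taken as 2. The direction of the ratio is not stated either. By a rule fixed before the data were examined, a positive value was read as sample over reference because USV1 was lower in the deletion at all 5 shared time points, and this direction is likely rather than known. The deposited medians of the arrays lay between -0.11 and 0.03, and the standard deviation (SD) over genes between 0.49 and 1.63. The table held 6100 open reading frames, of which 5362 had a value on all 12 arrays and none had fewer than 10 values. Depth has no meaning for these arrays, and their number limits the precision. No columns of other samples were present (0).

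Gene names came from matching the systematic names to locus tags of a RefSeq table of assembly R64, used only for names and neighbours. It matched 5592 genes, and the other 508 are called by their systematic name. Spotted probes of near-identical genes can bind each other's transcripts, so values of paired ribosomal protein genes and of TDH, HXT, PAU, COS, Y-prime and Ty genes are uncertain.

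Each array was centred to a median of 0. The strain effect (deletion minus wild type) came from limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the 10 arrays at the 5 time points that both strains share, with time point as a factor. The time effect (1 day minus 0 hours) came from the same fit, with 2 arrays per time point, 1 of each strain. Trends were slopes per time step over all 12 arrays, with a separate intercept and slope for each strain and a shared residual spread. The 2-hour array of the deletion and the 3-hour array of wild type shared step 2 of the 6 steps. The trend difference was the deletion slope minus the wild-type slope. A gene entered the strain and time effects with at least 4 of 5 values per strain and, for the time effect, values on all arrays of the 2 time points. It entered the trends with at least 5 of 6 values per strain. P-values were adjusted over all genes tested (Benjamini-Hochberg) and called at 0.05. Standard errors (SE) are those of the moderated fit. For the strain effect, p-values measure how steady the difference was over time points. For the time effect, they set the change against the scatter of the strain difference over the 5 shared time points. For the trends, they set the slope against departures from a straight line over the steps.

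A total of 28 gene lists was fixed before the data were examined, from textbook knowledge of diauxic and stationary phase yeast, with marker genes of mating type, sporulation and selection and the 5 neighbours of USV1. Of their 571 entries, 2 had no match. Lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. Genes named in the text followed a rule fixed at the same time. It took USV1 and its 5 neighbours, and then up to 10 genes with the largest rise and up to 10 with the largest fall among those past the threshold (changed the same way in both strains for the time effect). Where none passed in a direction, it took the 5 with the smallest p, given as values and not as changes. It also took the 2 members of each list with the largest change past the threshold. Other genes named in the text were chosen after their values were seen, as is said there. At each time point a list's median difference was also placed among 10000 random lists of the same size, which were not matched on expression because the table holds no intensities.

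The fits were tested on simulated data with 50 genes changed at each of 4 sizes. Of 50 genes shifted by a log2 of 1, 2, 3 and 4, the strain effect recovered 17, 39, 46 and 48, the time effect 2, 15, 44 and 43, and the trend difference, with the shift as the total over the course, 0, 9, 22 and 38. False calls numbered 4, 3 and 5. The simulated noise was independent between genes, whereas in the data the estimated correlation within ribosomal proteins was 0.91. Many genes were changed at once, which eases the adjusted threshold. In the data USV1, at -2.63 for the strain effect, had adjusted p = 0.814 (limma), so the recovered numbers may be too high for these data. Alternatives were the values as deposited, quantile normalization, other rules for missing values, a robust variance prior, other time points, each time point or array left out, a fold threshold, a plain paired test and early against late arrays in place of a slope. A few alternatives, named in the closing section, were added after the data were seen. Figures were drawn from the same values.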

Results

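The expression of 6100 open reading frames was measured on 12 arrays, 6 of wild-type yeast and 6 of a strain lacking USV1, over a course that the labels call stationary phase and that ran to 1 day. The course addresses how expression changes as cells stop growing and whether loss of USV1 alters it. No time point was repeated within a strain. Between 5931 and 6085 genes had a value on each array. Values are log2 ratios to the reference, centred per array, and a positive value was taken as sample over reference.

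The direction of the ratio was taken from USV1, so its sign does not check the labels. Its log2 ratio in wild type was -0.57 at 0 hours, 0.50 at 3 hours and 0.28 at 5 hours, then 4.40 at 7 hours, 3.94 at 9 hours and 2.59 at 1 day. In the deletion strain it was -1.0 at 0 hours, -2.46 at 2 hours, -1.40 at 5 hours, 1.14 at 7 hours, -0.98 at 9 hours and -0.29 at 1 day. It was lower in the deletion at all 5 shared time points, by 0.43 at the least and 4.92 at the most on the log2 scale. The spot still gave a ratio of 1.14 at 7 hours in the strain that lacks the gene, and the sequence it carries was not used here.

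Both strains passed through a large shift in expression, which fell at different labelled times. In wild type, 248 genes differed at least 2-fold between 0 and 3 hours and 277 between 3 and 5 hours, against 2011 (34.2%) between 5 and 7 hours. In the deletion strain, 113 genes differed at least 2-fold between 0 and 2 hours and 2559 (43.1%) between 2 and 5 hours, against 698 between 5 and 7 hours. The median of 135 cytosolic ribosomal protein genes was 0.08 in wild type and -3.46 in the deletion at 5 hours, and -3.50 and -2.92 at 7 hours. Stress-induced stationary phase genes had medians of 0.72 in wild type and 4.07 in the deletion at 5 hours, and 3.66 and 4.38 at 7 hours. Across genes, the 5-hour array of the deletion correlated at r = 0.907 with the 7-hour array of wild type and at r = 0.478 with the 5-hour array of wild type; genes are not independent replicates. These are values of single arrays with no test.

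**Figure D1:**
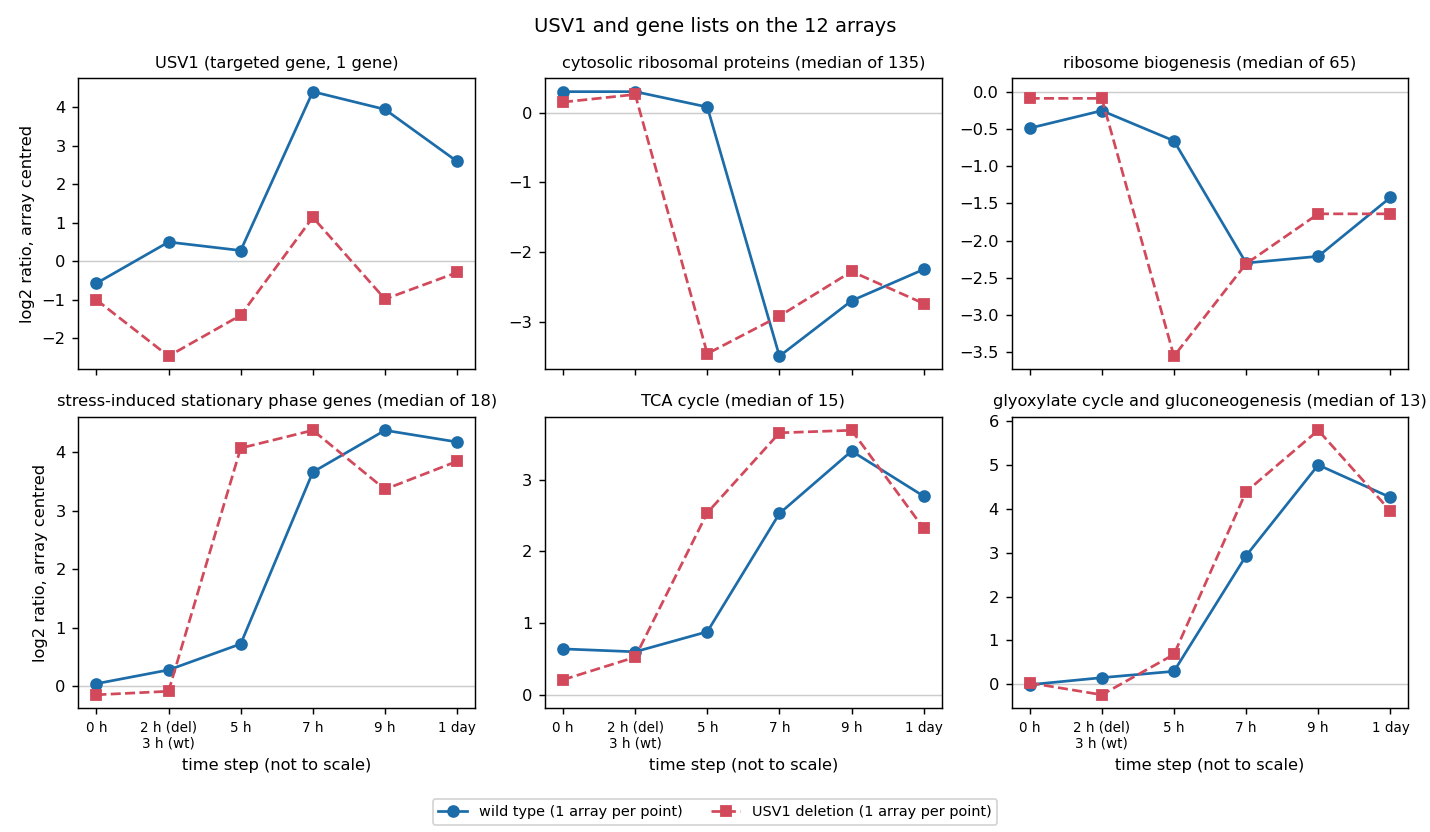
Log2 ratio to the reference (array centred, vertical axis) of USV1 and the medians of 5 gene lists at each time step (horizontal axis, not to scale), with circles and solid lines for wild type and squares and dashed lines for the USV1 deletion, 1 array per point and no error bars. The ribosomal protein median dropped to -3.46 at 5 hours in the deletion and to -3.50 at 7 hours in wild type.

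**Figure D2:**
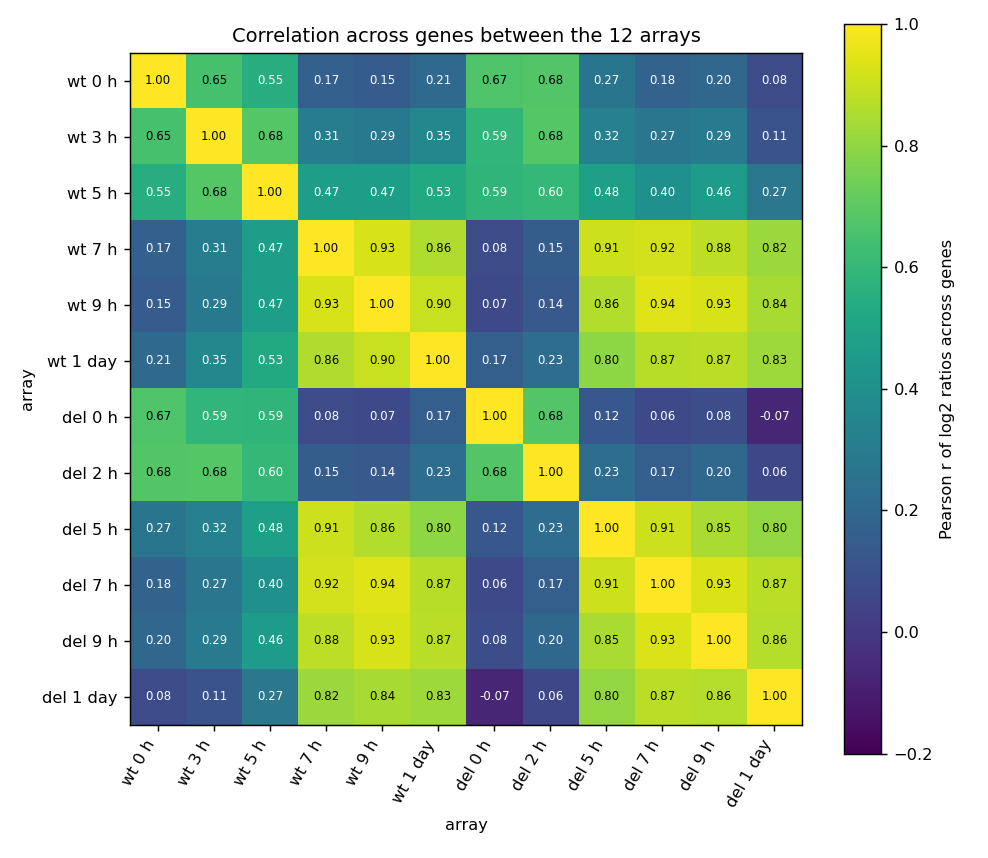
Pearson correlation across genes between the log2 ratios of each pair of the 12 arrays (colour and printed value), with wild type (wt) and the USV1 deletion (del) labelled by time on both axes. The 5-hour array of the deletion lies at 0.91 with the 7-hour arrays of both strains.

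From 0 hours to 1 day, 252 of 5838 genes tested passed, with 181 higher and 71 lower at 1 day (limma, n = 2 arrays per time point). Those that rose included 22 of 35 genes of the respiratory chain and ATP synthase, 8 of 13 of the glyoxylate cycle and gluconeogenesis and 7 of 17 stress-induced stationary phase genes. Those that fell included 6 of 36 cell wall genes, 5 of 135 ribosomal protein genes, 3 of 18 glycolysis genes and 3 of 22 ergosterol genes. The 10 largest rises were led by GRE1, a hydrophilin induced by osmotic stress, at a log2 change of 7.54 (SE 1.17, adjusted p = 0.0203), HSP30, a stress protein of the plasma membrane, at 7.37 (SE 1.39, adjusted p = 0.0314), SPS100, known from spore wall maturation, at 6.88 (SE 0.69, adjusted p = 0.00431), and HSP12, a membrane-protecting stress protein, at 6.81 (SE 0.89, adjusted p = 0.00978). The others were SPG4 (6.35), the hexose transporter HXT5 (5.84, uncertain for its family), the small heat shock protein HSP26 (5.61), the hydrophilin SIP18 (5.55), ECM13 (5.41) and the lactate permease JEN1 (5.30), all with an adjusted p at or below 0.0314. SPG4 and JEN1 had no value on the 5-hour wild-type array, so their p-values do not take in the strain difference at 5 hours.

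The 10 largest falls ran from 3.60 to 4.21 on the log2 scale. INA1 and RPL5, a protein of the large ribosomal subunit, fell by 4.21 (SE 0.84 and 0.89), and CYS3, an enzyme of cysteine synthesis, fell by 4.05 (SE 0.68). RPP0, the ribosomal stalk protein, fell by 4.02 (SE 0.85), ASC1, a protein of the small ribosomal subunit, by 3.80 (SE 0.75), and UTR2, a cell wall glycosidase, by 3.75 (SE 0.61). TEF4, a translation elongation factor, fell by 3.66 (SE 0.74), ERG6, a sterol methyltransferase, by 3.62 (SE 0.61), and RPL3 by 3.60 (SE 0.69). YLR339C fell by 3.65 (SE 0.75) and is uncertain, since it adjoins RPP0. Adjusted p-values of these 10 genes ran from 0.0227 to 0.0411.

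Camera at the preset correlation called 5 lists of energy metabolism and its regulators higher at 1 day, and none of them with an estimated correlation (adjusted p = 0.253 to adjusted p = 0.395). Of 35 respiratory chain and ATP synthase genes, 22 rose (33 adjusted over the list alone), with a median of 2.60, among them COX12 (4.17, SE 0.36) and QCR8 (4.13, SE 0.52). In the tricarboxylic acid cycle 7 of 15 genes rose (9 adjusted over the list alone), among them the succinate dehydrogenase subunits SDH2 (4.18) and SDH4 (3.48). Of 13 genes of the glyoxylate cycle and gluconeogenesis 8 rose (11 adjusted over the list alone), with a median of 4.46, including JEN1 and the acetyl-CoA synthetase ACS1 (4.91, SE 0.52). In fatty acid beta-oxidation and peroxisomes 5 of 18 rose (11 adjusted over the list alone), with the carnitine acetyltransferase CAT2 at 5.18 and the carnitine carrier CRC1 at 5.07. Of 25 glucose and stress regulators 3 rose (6 up and 1 down adjusted over the list alone), among them SIP4, an activator of gluconeogenic genes, at 4.10 and HAP4, an activator of respiratory genes, at 3.34. Without the 5-hour arrays, at the same medians, 33 of 35 respiratory, 11 of 15 tricarboxylic acid cycle, 12 of 13 glyoxylate and gluconeogenesis and 15 of 18 beta-oxidation genes rose, and of the 25 regulators 12 rose and 1 fell. Without the 7-hour arrays these counts were 10, 0, 9 and 2, with 1 regulator up.

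Camera called 6 lists of stress protection, storage, nitrogen and the vacuole higher, and none of them with an estimated correlation (adjusted p = 0.321 to adjusted p = 0.536); most of their members did not pass. Of 17 stress-induced stationary phase genes 7 rose (16 adjusted over the list alone), with a median of 4.17. In trehalose and glycogen metabolism 1 of 19 rose (4 adjusted over the list alone), the acid trehalase ATH1 at 2.81. Of 22 heat shock proteins and chaperones 4 rose and 18 did not pass (7 up and 2 down adjusted over the list alone). In oxidative stress defence 2 of 19 rose, the catalase CTT1 (5.11) and the peroxiredoxin PRX1 (3.50), and 1 fell (6 up and 3 down adjusted over the list alone). Of 23 genes repressed by good nitrogen sources 8 rose (12 up and 1 down adjusted over the list alone), including the proline permease PUT4 (5.04, SE 0.35) and the proline oxidase PUT1 (4.05). PUT4 had no value on the 5-hour wild-type array, so its SE does not take in the strain difference at 5 hours. None of 24 genes of vacuolar proteases and autophagy passed alone (0 also over the list alone), and their median was 0.96. Without the 5-hour arrays, at the same medians, 15 of 17 stress-induced, 13 of 19 trehalose and glycogen and 11 of 24 vacuolar and autophagy genes rose, as did 9 heat shock genes (2 fell), 10 of oxidative stress defence (4 fell) and 12 of the nitrogen list (1 fell). Without the 7-hour arrays 2 stress-induced, 3 heat shock and 3 nitrogen genes rose and 0 in the other 3 lists.

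Camera called 8 lists lower, and none of them with an estimated correlation (adjusted p = 0.321 to adjusted p = 0.536); most of their members did not pass. Of 135 cytosolic ribosomal protein genes 5 fell over all genes tested and 114 adjusted over the list alone, and all 135 had a negative estimate, with a median of -2.83; values of paired genes are uncertain. In ribosome biogenesis 0 of 65 passed either way, with 63 estimates below 0 and a median of -1.27. Of 18 glycolysis and fermentation genes 3 fell (9 adjusted over the list alone), among them the pyruvate decarboxylase PDC1 (-3.03, SE 0.54) and the pyruvate kinase CDC19 (-2.02, SE 0.36). CDC19 had no value on the 5-hour deletion array, so its SE does not take in the strain difference at 5 hours. Of 36 cell wall genes 6 fell (3 up and 9 down adjusted over the list alone), with UTR2 and SUN4 (-3.45) in the lead, and of 22 ergosterol genes 3 fell (8 adjusted over the list alone), with ERG6 and ERG13 (-2.69). Of 43 amino acid biosynthesis genes 3 fell and 1 rose (2 up and 9 down adjusted over the list alone), with BAT1 at -3.48 and the arginine gene ARG3 at 2.79. Of 7 a-cell genes 1 fell, the protease BAR1 (-2.50), and 2 adjusted over the list alone, while 0 of 9 histone genes passed, with a median of -0.97. Without the 5-hour arrays, at the same medians, 133 of 135 ribosomal protein, 41 of 65 ribosome biogenesis (1 rose), 10 of 18 glycolysis (2 rose), 19 of 36 cell wall (4 rose), 10 of 22 ergosterol, 16 of 43 amino acid (5 rose), 5 of 7 a-cell and 5 of 9 histone genes fell. Without the 7-hour arrays 2 cell wall genes fell, 1 amino acid gene rose and 0 passed in the other 6 lists.

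In all, camera at the preset correlation called 19 lists, 11 up and 8 down. Fry called 11 lists, 9 of them among the 19. The other 9 lists were not called by camera, and fry called 2 of them lower, haploid and pheromone genes (adjusted p = 0.0443) and the neighbours of USV1 (adjusted p = 0.0493). Hexose transporters had 2 of 9 up (HXT5 and HXT6, at 3.59) and 1 down, phosphate starvation genes 1 of 13 down (PHO11, -3.07), iron regulon genes 1 of 15 down (FET3, -3.06), haploid and pheromone genes 1 of 12 down (SST2, -1.97) and sporulation genes 1 of 14 up (SPS100). No member passed among 29 proteasome genes, 3 alpha-cell genes, 5 selection marker genes and the 5 neighbours of USV1. Without the 5-hour arrays these 9 lists had at most 3 members up and at most 5 down each, and without the 7-hour arrays 1 sporulation gene rose and no other member passed.

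The count depended on the time points in the fit, since they set its residual spread: it was 1801 without the 5-hour arrays (887 up and 914 down, all 252 among them) and 51 without the 7-hour arrays (47 up and 4 down). Of the 10 largest rises 6 were still called without the 7-hour arrays (SPS100, HSP12, SPG4, HSP26, ECM13 and JEN1), and of the 10 largest falls 1 (UTR2). The balance of 181 up to 71 down was 174 to 123 with the values as deposited and 768 to 730 after quantile normalization. Against 0 hours, 0 of 5891 genes passed at 5 hours (limma, 856 at an unadjusted p under 0.05), 654 at 7 hours (346 up, 308 down) and 244 at 9 hours (180 up, 64 down). The 5-hour contrast pools unlike arrays, with 536 genes at least 2-fold from their own 0 hours in wild type and 2632 in the deletion. Its 0 therefore does not show that little had changed by 5 hours.

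Within each strain, slopes per time step passed for 313 of 6011 genes in wild type (172 up, 141 down) and for 275 in the deletion (175 up, 100 down). GRE1 had slopes of 1.64 (SE 0.32, adjusted p = 0.0253) in wild type and 1.66 (SE 0.32, adjusted p = 0.0316) in the deletion, and COX12 of 0.99 and 0.95 (SE 0.13 each). CYS3 fell by 0.93 and 0.96 per step and ERG6 by 0.82 and 0.75. A total of 110 genes passed in both strains, all 110 in the same direction, where independent lists of these sizes would share 7.35. Both slopes come from a fit that shares each gene's residual variance, so 7.35 is not the overlap to be found with no shared change. Slopes correlated at r = 0.879 across genes. USV1 had a slope of 0.86 (SE 0.27, adjusted p = 0.0740) in wild type and 0.30 (adjusted p = 0.474) in the deletion, and neither passed.

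Single arrays moved these counts. For wild type the count was 1044 without the 5-hour array of the deletion, 0 without the wild-type array at 0 or at 3 hours, 1 without that at 9 hours, 32 without that at 1 day and 107 without that at 5 hours, and 135 and 128 without the deletion arrays at 0 and 9 hours. For the deletion it was 1158 without its own 5-hour array, 0 without that at 0 hours, 1 without that at 2 hours, 99 without that at 7 hours, 126 without that at 9 hours and 65 without that at 1 day, and 108, 25 and 120 without the wild-type arrays at 0, 3 and 9 hours. With the values as deposited the split was 164 up to 176 down in wild type and 152 to 154 in the deletion, and after quantile normalization 384 to 468 and 675 to 696.

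Between the strains, averaged over the 5 shared time points, no gene passed, USV1 included. USV1 differed by -2.63 (deletion minus wild type, SE 0.56, unadjusted p = 0.00138, adjusted p = 0.814, limma) and was lower at 5 of 5 time points. Its neighbours on the chromosome were ALG5 at -1.10 (SE 0.56), CET1 at 0.41 (SE 0.22), YPL229W at 0.47 (SE 0.29), FAS2 at 0.28 (SE 0.27) and SSO1 at -0.08 (SE 0.26). Single time points moved these values: without 7 hours ALG5 stood at -0.56 and FAS2 at 0.085, without 5 hours FAS2 stood at 0.475 and SSO1 at -0.27, and without 0 hours SSO1 stood at 0.0625. Among genes higher in the deletion the smallest p-values belonged to WSC4, a cell wall sensor (1.55, SE 0.29), AHK1, a scaffold of the osmotic stress pathway (1.08, SE 0.25), ACS1 (1.30, SE 0.33), QRI7 (0.88, SE 0.23) and YER188W (1.05, SE 0.28). AHK1 had no value at 0 hours in wild type, so its estimate leaves out that time point. Among genes lower in the deletion the smallest p-values belonged to USV1, YLR162W (-1.58, SE 0.38), YNL303W (-1.06, SE 0.25), MFA2, a gene of the a-factor pheromone (-0.88, SE 0.24), and the glycolytic gene PGK1 (-0.80, SE 0.23). All genes named for their smallest p-values had adjusted p = 0.814 (limma). Of 6062 genes, 260 had an unadjusted p under 0.05 (164 higher, 96 lower), and a plain paired test gave 293 and 0 after adjustment. Both counts are below the share of 0.05 to be found on average with no strain difference. The 260 became 428 of 6077 without 0 hours and 415 of 6082 without 5 hours, both above a share of 0.05. Counts below that share were 115 without 7 hours, 85 without 1 day and 154 with time point left out of the fit. At 7 hours, 9 hours and 1 day alone, 676 of 6091 genes had an unadjusted p under 0.05 (limma), also above a share of 0.05. Of these genes 2 passed, USV1 (-3.69, SE 0.37, adjusted p = 0.000822) and YLR162W (-2.12, SE 0.30, adjusted p = 0.0199), both lower in the deletion. Genes are not independent replicates, so a share above or below 0.05 is not a test.

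The distance between the strains was greatest at 5 hours, when 1228 genes were at least 2-fold higher and 1207 at least 2-fold lower in the deletion. The number of genes at least 2-fold apart was 222 at 0 hours, 2435 at 5 hours, 471 at 7 hours, 380 at 9 hours and 1068 at 1 day. At 5 hours the median difference was -3.47 for ribosomal protein genes (133 of 134 measured members lower), -2.84 for ribosome biogenesis (64 of 65 lower), 3.03 for trehalose and glycogen metabolism (19 of 19 higher), 2.91 for stress-induced stationary phase genes and 1.92 for beta-oxidation, the last 3 each at percentile 100 of random lists. For the glyoxylate cycle and gluconeogenesis it was 0.50 (7 of 12 higher). At 7 hours ribosomal protein genes stood at 0.48, the tricarboxylic acid cycle at 1.10 and the glyoxylate and gluconeogenesis list at 1.07. At 9 hours stress-induced stationary phase genes stood at -0.90 (16 of 18 lower), and at 1 day ribosomal protein genes at -0.40 (100 of 135 lower).

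**Figure D3:**
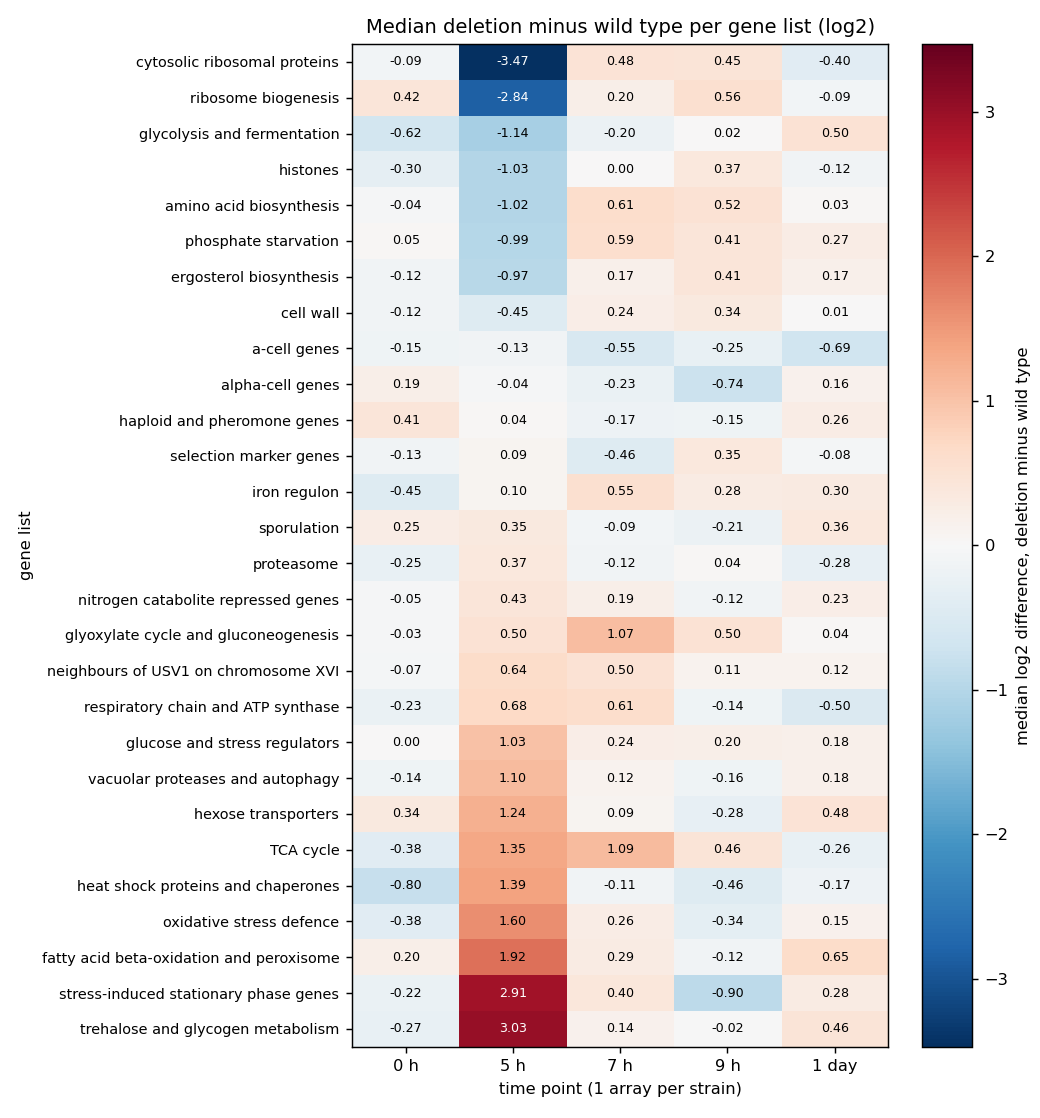
Median log2 difference (deletion minus wild type, colour and printed value) of the members of each of 28 gene lists (vertical axis) at the 5 shared time points (horizontal axis), 1 array per strain and time point, with lists in the order of their 5-hour value. The 5-hour column holds the extremes, from -3.47 for ribosomal proteins to 3.03 for trehalose and glycogen metabolism.

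Over the 5 time points camera at the preset correlation called 11 of 28 lists. Higher in the deletion were the tricarboxylic acid cycle (median 0.39), the glyoxylate cycle and gluconeogenesis (0.38), beta-oxidation (0.65), trehalose and glycogen metabolism (0.53), stress-induced stationary phase genes (0.48), vacuolar proteases and autophagy (0.24) and the regulators (0.30). Lower were ribosomal proteins (-0.61), ribosome biogenesis (-0.36), glycolysis and fermentation (-0.22) and a-cell genes (-0.46). None was called with an estimated correlation, at adjusted p = 0.828 at the lowest, or with fry, at 0.628. Without the 5-hour arrays the glyoxylate and gluconeogenesis (0.46), beta-oxidation (0.25) and a-cell (-0.32) lists were called in the same direction, ribosome biogenesis was called in the opposite direction (0.28), and ribosomal proteins (0.10) and stress-induced genes (-0.21) took the opposite sign without being called. The tricarboxylic acid cycle (0.21), trehalose and glycogen metabolism (0.05), autophagy (0.0013), glycolysis (-0.12) and the regulators (0.31) also lost their call, while heat shock proteins (-0.40), the proteasome (-0.18) and amino acid biosynthesis (0.27) gained it. Other time points ended calls too: without 7 hours those of the glyoxylate list (adjusted p = 0.130), a-cell genes (adjusted p = 0.194), the tricarboxylic acid cycle and stress-induced genes (adjusted p = 0.0609 each), without 0 hours those of glycolysis (adjusted p = 0.223) and a-cell genes (adjusted p = 0.0534), and without 9 hours that of a-cell genes (adjusted p = 0.0931).

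A difference in slope between the strains was not shown, and slopes say little of a difference in timing such as that at 5 hours. No gene of 6011 passed for the difference of slopes (limma, lowest adjusted p = 0.9998, 216 at an unadjusted p under 0.05, which became 98 without the wild-type array at 0 hours, 113 without the deletion array at 1 day, 98 without both arrays at 1 day, 116 as early against late and 325 after quantile normalization), and 0 of 28 lists were called by camera or fry. The 216 genes are also below a share of 0.05 of the 6011. Slope differences with the smallest p were 0.52 for INP51, 0.41 for COT1, 0.37 for RSC4, 0.33 for YEL075C (uncertain, near Y-prime genes) and 0.54 for VTC1 on the higher side. On the lower side they were -0.42 for ISD11, -0.51 for GMC2, -0.43 for EUC1, -0.39 for YLL037W and -0.38 for CTK2, with SEs from 0.10 to 0.17 over the 10 genes. USV1 had a slope difference of -0.56 (SE 0.39). Simulated shifts of a log2 of 2 over the course were recovered for 9 of 50 genes, so differences of that size would mostly have been missed.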

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

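The comparison of the 5-hour deletion array with the late wild-type arrays and with the later deletion arrays was chosen only after that array's values were seen. Of 38 sets of 4 to 6 values examined, 6 held a value far from the rest. Chance gives about 1 in 20 for independent sets, but most of these sets were list medians from the same arrays. The 5 list values flagged come from 1 pair of arrays, so they restate 1 difference. The median differences between the strains (deletion minus wild type) stood apart at 5 hours for 5 lists. They were -3.47 for ribosomal proteins, where the other 4 time points lay between -0.40 and 0.48, and -2.84 for ribosome biogenesis, where they lay between -0.09 and 0.56. They were 3.03 for trehalose and glycogen metabolism (others -0.27 to 0.46), 1.10 for vacuolar proteases and autophagy (others -0.16 to 0.18) and 1.03 for glucose and stress regulators (others 0.00 to 0.24). The 2-hour array of the deletion measured 5958 genes, against 6069 to 6084 on the other deletion arrays. It lay within the range of the wild-type arrays, 5931 to 6085.

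The strains differed most at 5 hours, where the deletion array carried low ribosomal and high stress transcripts. The array resembles the profile of the wild-type arrays at 7 hours, 9 hours and 1 day. Wild-type RNA in the state of those 3 arrays is argued against by USV1, at -1.40 on this array and 2.59 or more on those. Wild-type RNA from a state that was not sampled cannot be excluded this way. In wild type USV1 lay between -0.57 and 0.50 up to 5 hours, and when it rose before 7 hours is not known. A repeat of a later deletion sample is argued against by the glyoxylate and gluconeogenesis genes. Their median difference from the 1-day deletion array, the nearest later deletion array on this list, was -2.49, with 11 of 13 members lower. Across all genes the nearest later deletion array was that at 7 hours (r = 0.907). A difference between the 2 cultures that has nothing to do with the deletion cannot be told apart from an effect of the deletion, because each strain has 1 array per time point and 1 course. An effect of losing USV1 stays open as well.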

How the results depend on the processing

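Leaving the 5-hour arrays out of the trends and of the time-effect lists, the late time points for the lists, and late against early arrays for the time effect were chosen after seeing the data. The strain effect and the trend difference stayed at 0 genes under every alternative run, except 2 genes at the 3 late time points; the block for time point left out also gave 0, and USV1 averaged -2.66 with the values as deposited. The time effect moved from 252 genes to 1498 after quantile normalization, to between 51 (without 7 hours) and 1801 (without 5 hours) with a time point left out, and to 3339 for 7 hours, 9 hours and 1 day against 0 hours and step 2. The wild-type trend (313) and the deletion trend (275) gave 852 and 1371 after quantile normalization, 940 and 82 as early against late, 0 and 0 without step 2, 665 and 1130 without the 5-hour arrays, and 0 to 1044 and 0 to 1158 with an array left out; the deletion trend gave 82 without 1 day. A time point left out leaves the estimates of complete genes for 1 day against 0 hours as they were and changes the spread, as does an array of the other strain left out of a trend; for the other settings the cause was not tested.

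Lists called for the strain effect numbered 11, but 0 with an estimated correlation, 0 with fry, 7 at the late time points, and 7 to 12 with a time point left out. Lists called for the time effect numbered 19, but 0 with an estimated correlation, 11 with fry, and 0 without the 5-hour arrays at an estimated correlation. With a time point left out, medians ran from -0.90 to 0.10 for ribosomal proteins, -0.58 to 0.28 for ribosome biogenesis, -0.21 to 0.71 for stress-induced genes and 0.0013 to 0.38 for autophagy, whose test turned sign, and the SSO1 difference ran from -0.27 to 0.0625. At the late time points medians were 0.23 for ribosomal proteins, 0.27 for ribosome biogenesis, 0.075 for glycolysis and -0.055 for stress-induced genes. The number of arrays limits precision, and signal over background was not given.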

Other observations

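The test of whether the 3 late differences are array scatter was chosen only after their correlations were seen. On the 5-hour array of the deletion, a stress and storage pattern stood beside some gluconeogenic transcripts that were not raised. The median of the glyoxylate and gluconeogenesis list was 0.68 there and 0.03 at 0 hours in the deletion. The genes in this paragraph were chosen after their values were seen. The glycogen synthase GSY1 stood at 5.63 and the trehalose genes TSL1 and TPS2 at 4.71 and 4.09, above every other array of either strain for each. The gluconeogenic genes PCK1 (-0.11) and FBP1 (-0.51) and the malate synthase MLS1 (-0.36) were near the reference level there, and stood at 4.88, 2.93 and 2.41 in wild type at 7 hours and at 5.39, 6.04 and 5.09 in the deletion at 7 hours. ICL1 (2.27), ACS1 (2.34) and JEN1 (3.84), of the same list, were raised at 5 hours in the deletion. Each value comes from a single array.

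At 7 hours, 9 hours and 1 day, 9 of 5742 genes differed at least 2-fold the same way between the strains at all 3 time points, and they too were chosen after their values were seen. Lower in the deletion were USV1 (mean -3.69, SD 1.08 over the 3 time points), YLR162W (-2.12, SD 0.47), the cell wall protein gene SPI1 (-1.71, SD 0.42) and the mitochondrial pyruvate carrier gene MPC2 (-1.16, SD 0.07). Higher were the cell wall mannoprotein gene CWP1 (1.81, SD 0.40), the aromatic decarboxylase gene ARO10 (1.57, SD 0.34), YJL213W (1.27, SD 0.13), the carnitine acetyltransferase gene YAT1 (1.24, SD 0.18) and the acid phosphatase gene PHO5 (1.16, SD 0.16). At 5 hours SPI1 was higher in the deletion by 3.90, CWP1 differed by -2.19 and PHO5 by -1.01, each opposite in sign to the late time points. Of the 4 patterns of signs over the 3 time points 1, the real one, gave 9 such genes and the highest other gave 5, and 4 patterns are too few for a share under 0.05. The mean correlation of the 3 differences across genes was 0.167 (0.153 to 0.180), although they share no array. It cannot decide whether array scatter alone underlies them, because genes are not independent replicates. Other pairs of strain differences, which share no array either, correlated at -0.358 to 0.313. Whether the deletion or the culture underlies the late differences was not tested.

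A hypothesis is that the deletion culture ran ahead of the wild-type culture over the whole course, which may account for part of the differences at 5 hours and later. If so, the strain difference at 7 and 9 hours should resemble later-minus-earlier changes on arrays that it does not use. The difference at 7 hours correlated at r = 0.175 across genes with the change from 5 to 9 hours in the deletion, and that at 9 hours at r = 0.255 with the change from 7 hours to 1 day in wild type. Both lie above the 0.1 set before they were computed, yet they are small, genes are not independent replicates, and neither says why a culture would run ahead. Strain differences that share no array correlated at -0.358 to 0.313, so 0.1 is a weak bar. At 1 day, which was not checked, lists went both ways. From 9 hours to 1 day in wild type the tricarboxylic acid cycle fell from 3.40 to 2.77, and the deletion stood further on at 2.32. Ribosomal proteins rose from -2.70 to -2.25, but the deletion stood lower at -2.74.

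For the strain effect, 41 of 100 splits of the 10 arrays into 5 and 5, the real split included, gave at least its 260 genes at an unadjusted p under 0.05, and the highest other gave 2060. The split with 2060 parts only the 5-hour pair, so its effect rests on 1 array against 1 and restates the difference at 5 hours. Many of the 100 splits part only 1 or 3 of the 5 pairs, and some repeat the same fit. The 41 of 100 is therefore not a chance share for the paired strain effect. Of the 16 exchanges of strain labels within time points, which keep the pairs, 8, the real labels included, gave at least the real 260, and the highest other gave 535. Chance cannot be excluded, and 16 are too few for a share under 0.05. For the trend difference, 5 of 32 exchanges within time steps, the real labels included, gave at least the real 216 genes, the highest other gave 334, and chance cannot be excluded.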
